A study of Mus musculus with 2 samples.

How the data were processed

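PolyA-plus RNA was measured in forebrain of mouse embryos (strain B6NCrl, mixed sex) at embryonic day 12.5, in 2 libraries that the labels call biological replicates. Pool 1 was made from 120 embryos and pool 2 from 68 embryos, with 10 ng of RNA per library. Per the labels' protocols, cDNA was primed with oligo-dT, made with a low-input kit that amplifies full-length cDNA by PCR, and fragmented by Nextera tagmentation, with ERCC spike-in RNAs added. ERCC spike-ins are a set of synthetic RNAs of known sequence. The labels give 1 group and no contrast, so levels with their spread over the 2 pools were reported, and differences between the pools were described without a test.

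The authors deposited gene and transcript tables per library for the mm10 assembly with GENCODE releases M4 and M21, and 8 of these tables were used. The deposited expected counts are estimated reads per gene or transcript, not normalised, in which reads with several matches are shared out. The deposited TPM values are abundances scaled to 1e6 per library over annotated transcripts, spike-ins and numbered entries. The deposited FPKM values are per kilobase of effective length and 1e6 assigned reads, per the file headers. The deposited posterior mean TPM and its interval bounds were treated as a score, because their rounded values can sum to slightly over 1e6, and the interval bounds are not reported here. The column names in the file headers follow the layout of RSEM, but the aligner, the quantifier and their versions are not given in the sources used here. Whether the counting used strand is also not given, so overlapping and antisense genes were treated as uncertain.

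The tables of release M21 were the main ones and those of M4 the alternative. All 55536 gene identifiers of the newer tables matched the GENCODE M21 annotation of GRCm38, which gave symbols, biotypes and coordinates. Of the 43346 gene identifiers of the older tables, 42462 matched it. Numbered entries that name no gene stayed out of library sizes and held 5.74e-05% of the counts of pool 1 and 9e-05% of those of pool 2. Gene counts came to 33373776 in pool 1 and 34406601 in pool 2. Floors are the TPM that 3 counts would give. Intervals of count ratios and shares are exact binomial intervals at 95%. Intervals and floors cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

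Genes with a TPM of at least 1 in both libraries were called detected. Agreement of the libraries was measured as Pearson's r of log2(TPM + 1) over genes with a mean TPM of at least 1. Expected counts were rounded to whole numbers for edgeR 4.0.16 (TMM normalisation, genes with a mean count of at least 10, intercept-only model), which gave the common dispersion as a biological coefficient of variation. DESeq2 1.42.0 gave size factors and gene-wise dispersions as alternatives. The other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A total of 42 gene lists were fixed before the data were examined, and 1 symbol was matched through a synonym (Drgx, present as Prrxl1). Each list was described by the number of detected members and by the median of the members' mean TPM, with its percentile among 10000 random lists of protein-coding genes of the same size. For 6 pairs of lists the mean log2(TPM + 1) of one was subtracted from that of the other within each library. Between the pools, each list was described by its median log2 ratio of TMM-normalised counts (scaled per library, prior count 1, pool 1 over pool 2) and by that median's percentile among 10000 random lists matched on expression in 20 bins.

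Genes to be named were fixed by rule before the data were examined. Of lists with 10 or fewer members any member may be named, and of longer lists the 4 highest and 2 lowest by mean TPM, plus a member that stands alone on its side of TPM 1. The rule adds the 10 nuclear protein-coding genes of highest mean TPM, the 5 genes at each end of the ratio between the pools and of the ratio between the annotations (mean TPM of at least 10), and 15 genes whose transcripts are described. Other genes are said to have been chosen after their values were seen. Values of 2 further genes that the rule allows are not reported here.

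The pool comparison was tested on simulated data with a coefficient of variation of 10%, with 19082 genes in the fit and 200 of the simulated genes changed. The recovered coefficient of variation was 11.0%. The median recovered fold was 1.51 for genes changed 1.5-fold and 1.94 for genes changed 2-fold. Of simulated lists of 12 genes drawn from all genes in the fit, changed genes included, 5.5% lay outside the central 95% of matched lists. Of lists of 12 genes changed 1.5-fold, 100% lay above the 97.5th percentile. Simulated genes varied independently, so these shares give no error rate for lists whose members move together. All 42 lists were looked at, and 6 further lists were used in the closing part, fixed after the data were first examined and before their values were seen. Alternatives were other TPM minimums, pseudocounts, filters, units, scalings, annotations and leaving out each library.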

Results

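Forebrain RNA of mouse embryos at day 12.5 was profiled in 2 pools, pool 1 from 120 embryos and pool 2 from 68 embryos. The forebrain at this stage holds the telencephalon, with its dorsal pallium and ventral subpallium, and the diencephalon. Gene counts came to 33373776 in pool 1 and 34406601 in pool 2. Levels are given in TPM, a transcript abundance scaled to a fixed total per library, as the mean of the pools, and every ± is an SD over n = 2 pools. The labels name 1 group and no contrast, so the questions addressed are which genes this tissue expressed, at what level, and how far the pools differed. With 2 pools an exact two-sided sign-flip test cannot go below p = 0.5, so no exact test could reach 0.05 and none was run.

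In the newer annotation the nuclear protein-coding gene with the highest TPM was Actb, the cytoplasmic beta-actin, at 10429 ± 1030.3 TPM (SD, n = 2). Genes of the neuronal and dividing cytoskeleton stood near it, with the tubulin Tuba1a at 5928 ± 206 TPM, the thymosin Tmsb4x at 4731 ± 53.2 TPM and the microtubule regulator Stmn1 at 3620 ± 117 TPM. Embryonic and adult-type globins were among the 10 highest, Hbb-y at 5847 ± 1209 TPM and Hba-a2 at 4429 ± 919 TPM. The imprinted gene Nnat (chromosome 2, 157560078 to 157562522, GRCm38) reached 4348 ± 320 TPM, the replication-dependent histone Hist1h2ap 4835 ± 61.0 TPM, the ferritin light chain Ftl1 4322 ± 2.99 TPM and the prolyl isomerase Ppia 3618 ± 48.5 TPM. Actb, Tuba1a, Hba-a2 and Hist1h2ap have near-identical copies, so their share of reads is uncertain. In the newer annotation 53.9% of Actb's TPM lay in Actb-209, a non-coding transcript of 241 bases that held 8.44% of its counts. In the older annotation Actb came to 5505 TPM, below Tuba1a at 6924 TPM and Hbb-y at 5859 TPM, so its level and rank depend on the annotation.

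At a TPM of at least 1 in both libraries, 15420 genes were detected, of which 12966 were protein-coding, or 58.9% of the 22028 annotated protein-coding genes. The detected set also held 361 lincRNAs, 399 antisense genes and 568 processed pseudogenes, and the last share sequence with their parent genes. A further 1397 genes passed TPM 1 in only 1 library. Across 16151 genes with a mean TPM of at least 1, the libraries correlated with Pearson's r = 0.987 and Spearman's rho = 0.987. This is a correlation across genes, which are not independent replicates. The biological coefficient of variation was 8.50% over 19063 genes, from edgeR's common dispersion. With spike-in totals as the scaling, chosen after the data were examined, it was 12.85%. The counts differed by more than counting noise alone, with a chi-square of 8.17 per gene, which does not tell biological from technical spread.

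Regional transcription factors of the telencephalon were expressed throughout. All 9 members of that list were detected in both pools, led by Lhx2 (ENSMUSG00000000247.11, chromosome 2, 38339281 to 38369733, GRCm38), a selector of cortical identity, at 164 ± 16.1 TPM (SD, n = 2). Nr2e1 stood at 81.3 ± 0.191 TPM and Nr2f1 at 77.8 ± 14.8 TPM. Pallial genes were detected in 12 of 12 cases, with the proneural factor Neurog2 at 129 ± 3.85 TPM, Pax6 at 86.6 ± 0.813 TPM and Emx1 at 62.8 ± 9.77 TPM, down to Dmrta2 at 7.13 ± 0.693 TPM. Subpallial genes were detected in 15 of 15 cases, with Dlx1 (chromosome 2, 71528113 to 71533981) at 198 ± 50.8 TPM, Dlx2 at 85.5 ± 25.8 TPM, Dlx5 at 66.6 ± 18.9 TPM and the GABA-synthesising enzyme Gad2 at 60.0 ± 4.06 TPM. Dlx1 and Dlx6 overlap antisense genes, so their counts are uncertain.

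Beyond the telencephalon, most diencephalon and hypothalamus genes were detected, and midbrain, hindbrain and Hox genes were not. Of the diencephalon and hypothalamus list, 9 of 10 members were detected, led by Tcf7l2 at 169 ± 4.94 TPM, Lhx9 at 31.9 ± 4.13 TPM and Gbx2 at 21.4 ± 0.573 TPM, while Six6 read 0.20 TPM in pool 1 and 1.27 TPM in pool 2. None of the 12 midbrain and hindbrain genes reached TPM 1 in either library. Their highest was En1 at 0.81 ± 0.170 TPM, and En2 had 0 counts in both libraries, which allows up to 0.041 TPM in pool 1 and 0.039 TPM in pool 2. None of the 39 Hox genes, which pattern the hindbrain and trunk, reached TPM 1, and the highest was Hoxd1 at 0.325 ± 0.120 TPM. On the log2(TPM + 1) scale the telencephalon list exceeded the midbrain and hindbrain list by 5.38 ± 0.03 (SD, n = 2), with the same sign in 2 of 2 pools. Pallium minus subpallium gave -0.33 in pool 1 and 0.31 in pool 2, a mean of -0.01 ± 0.45, so neither list exceeded the other by more than the spread between pools. Differences on this scale understate those of low genes.

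**Figure D1:**
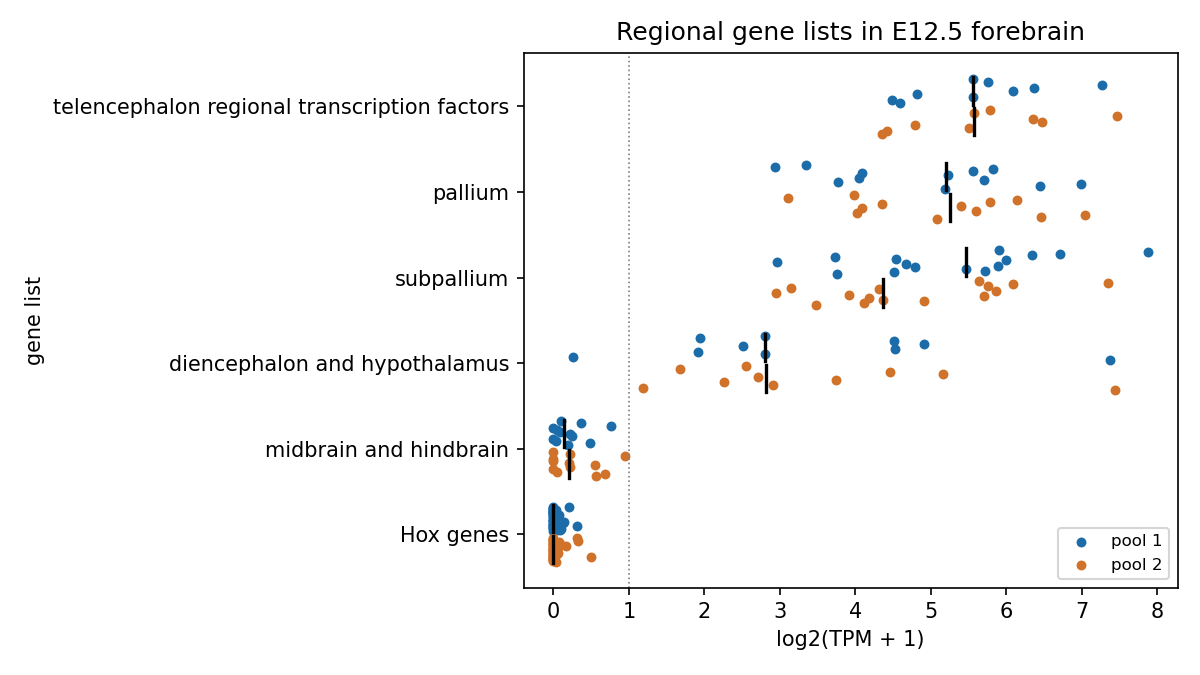
The x axis gives log2(TPM + 1) and each point is 1 gene of a regional list, blue for pool 1 and orange for pool 2, with a black line at the list's median and a dotted line at TPM 1. The telencephalon, pallium and subpallium points lie right of the dotted line, and all 12 midbrain and hindbrain genes and 39 Hox genes lie left of it.

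Most cortical hem and choroid plexus genes were detected, and most eye genes were not. Of the cortical hem list 5 of 6 members were detected, led by Rspo2 at 15.5 ± 2.33 TPM and Wnt5a at 14.3 ± 2.36 TPM. Of the choroid plexus list 4 of 5 were detected, with transthyretin (Ttr) at 62.3 ± 28.7 TPM and Folr1 at 5.33 ± 1.51 TPM. Of the eye list only the pigment-cell gene Dct was detected in both libraries, at 9.85 ± 0.573 TPM, and the lens crystallin Cryaa and the photoreceptor factor Crx had 0 counts.

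Progenitor and neuron genes were both strongly represented. All 13 radial glia and neural progenitor genes were detected, with the intermediate filament Vim at 856 ± 10.3 TPM (SD, n = 2), the fatty acid binding protein Fabp7 at 831 ± 103 TPM, the Notch effector Hes5 at 359 ± 2.33 TPM and Sox9 at 132 ± 18.3 TPM. All 11 intermediate progenitor genes were detected, led by Hes6 at 231 ± 1.99 TPM and Gadd45g at 167 ± 4.28 TPM. All 18 postmitotic neuron genes were detected, with the neuronal tubulin Tubb3 (chromosome 8, 123411424 to 123422015) at 674 ± 36.9 TPM, Dpysl3 at 332 ± 23.96 TPM, Crmp1 at 296 ± 28.5 TPM and Map2 at 277 ± 15.5 TPM, down to Rbfox3 at 14.3 ± 1.46 TPM. The medians of these lists, 82.6, 73.2 and 109 TPM, lay at the 100th, 99.9th and 100th percentile of random lists. Radial glia minus postmitotic neurons came to -0.07 ± 0.01 on the log2(TPM + 1) scale.

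Cell-cycle genes were high and close between pools. All 14 S phase genes were detected, with the ribonucleotide reductase subunit Rrm2 at 414 ± 4.94 TPM, the sliding clamp Pcna at 258 ± 7.85 TPM and the helicase subunit Mcm7 at 247 ± 3.26 TPM. All 16 G2 and M phase genes were detected, with Ube2c at 474 ± 4.71 TPM, Cdk1 at 298 ± 2.31 TPM, Top2a at 282 ± 5.96 TPM and Mki67 at 51.1 ± 2.34 TPM. The list medians of 162 and 129 TPM both lay at the 100th percentile of random lists.

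Gene lists of neuronal subtypes differed in level, which in bulk RNA does not measure the cells themselves. All 8 Cajal-Retzius genes were detected, led by Nhlh2 at 45.3 ± 1.84 TPM and Calb2 at 28.9 ± 6.14 TPM, with the secreted guidance protein Reln at 20.2 ± 1.08 TPM. All 7 GABAergic interneuron genes were detected, led by the peptides Sst at 34.7 ± 1.25 TPM and Npy at 20.1 ± 0.714 TPM, with the vesicular transporter Slc32a1 at 3.16 ± 0.255 TPM. Of the glutamate list 6 of 7 were detected, and the vesicular transporter Slc17a6 at 30.4 ± 0.474 TPM exceeded Slc17a7 at 5.55 ± 0.856 TPM and Slc17a8 at 0.38 ± 0.099 TPM. Of the monoaminergic and cholinergic list 2 of 8 were detected, the enzymes Th at 12.4 ± 2.16 TPM and Ddc at 5.84 ± 0.247 TPM, while Dbh had 0 counts.

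Genes of the astrocyte and oligodendrocyte lineage lists ranged widely in level, with list medians of 1.005 and 2.08 TPM. In the astrocyte list 3 of 6 members were detected. The gap junction gene Gja1 stood at 94.8 ± 9.10 TPM and Aldoc at 22.9 ± 2.54 TPM, but Aqp4 at 0.41 ± 0.028 TPM and Gfap at 0.045 ± 0.035 TPM. Radial glia minus astrocytes came to 4.17 ± 0.08 on the log2(TPM + 1) scale (SD, n = 2), and to 2.26 when only members with a mean TPM of at least 1 entered. In the oligodendrocyte lineage list 5 of 8 members were detected, among them Mbp at 12.3 ± 2.36 TPM and Olig1 at 8.48 ± 1.05 TPM, and the mature myelin gene Mag stood at 0.185 ± 0.120 TPM.

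Every member of the fixed signalling pathway lists was detected, though each list holds only some genes of its pathway. For Notch 11 of 11 members passed, led after Hes5 by the ligand Dll1 at 73.2 ± 4.65 TPM and Rbpj at 54.1 ± 1.32 TPM. For Hedgehog 9 of 9 passed, with Gas1 at 114 ± 7.50 TPM, Gli3 at 37.3 ± 0.672 TPM and the ligand Shh at 2.69 ± 0.785 TPM. For Wnt 10 of 10 passed, with Ctnnb1 at 601 ± 4.02 TPM, Wnt7b at 94.1 ± 10.9 TPM and Wnt8b at 23.9 ± 6.92 TPM. For Fgf 12 of 12 passed, with Fgfr3 at 76.0 ± 15.2 TPM, Fgf15 at 64.0 ± 13.1 TPM and Fgf8 at 3.60 ± 0.035 TPM. For Bmp 10 of 10 passed, with the inhibitor of bHLH factors Id4 at 184 ± 4.19 TPM, Id3 at 156 ± 30.7 TPM and Msx1 at 42.3 ± 15.4 TPM.

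Subunits of the BAF chromatin remodelling complex that are exchanged as progenitors become neurons were present in both forms. The progenitor subunits Actl6a at 181 ± 0.912 TPM and Dpf2 at 151 ± 9.78 TPM exceeded the neuronal subunits Dpf1 at 103 ± 15.8 TPM and Actl6b at 61.1 ± 2.20 TPM, while the progenitor subunits Ss18 at 79.7 ± 1.41 TPM and Phf10 at 19.8 ± 1.88 TPM were below Dpf1. The 4 progenitor subunits exceeded the 4 neuronal ones by 1.38 ± 0.10 on the log2(TPM + 1) scale, in 2 of 2 pools. All 15 neural RNA-binding protein genes were detected, with the splicing repressors Ptbp2 at 312 ± 9.14 TPM and Ptbp1 at 174 ± 0.332 TPM, Elavl1 at 242 ± 0.948 TPM and Nova2 at 8.61 ± 0.255 TPM. Elavl1 read 118 TPM in the older annotation.

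Transcripts of non-neural cells were measurable. The 11 erythroid genes were all detected and summed to 12687 TPM in pool 1 and 16993 TPM in pool 2, or 1.27% and 1.70% of TPM, a mean of 14840 ± 3045 TPM (SD, n = 2). Besides Hbb-y and Hba-a2 they included Hba-x, an embryonic globin, at 1077 ± 257 TPM. Mesenchyme and meninges genes were detected in 13 of 13 cases, with the collagens Col3a1 at 301 ± 20.1 TPM and Col1a1 at 185 ± 33.2 TPM. Postmitotic neurons exceeded this list by 2.14 ± 0.31 on the log2(TPM + 1) scale. All 10 endothelial genes were detected, led by Kdr at 19.6 ± 0.750 TPM and Cldn5 at 19.2 ± 0.191 TPM. All 5 pericyte genes were detected, led by Pdgfrb at 13.8 ± 1.22 TPM. Microglia and macrophage genes were detected in 12 of 13 cases, with the complement gene C1qb at 13.6 ± 1.58 TPM and the leukocyte marker Ptprc at 0.73 ± 0.127 TPM.

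Further cell types differed in how many of their genes were detected. Of the surface epithelium list 7 of 8 were detected, led by Epcam at 18.1 ± 2.90 TPM. Of the neural crest and Schwann cell list 2 of 4 were detected, Erbb3 at 1.56 ± 0.007 TPM and Tfap2a at 1.40 ± 0.247 TPM. Of the skeletal muscle list Actc1 alone was detected in both libraries, at 3.58 ± 2.05 TPM, and of the sensory ganglia list Pou4f1 alone, at 2.74 ± 1.41 TPM. None of the 6 pluripotency genes was detected, and the highest was Esrrb at 0.24 ± 0.113 TPM.

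Among imprinted genes 15 of 16 were detected, with Mest at 683 ± 78.2 TPM, the non-coding Meg3 at 506 ± 61.4 TPM and Grb10 at 282 ± 15.9 TPM after Nnat. The exception was Zim1 at 0.755 ± 0.177 TPM. Both X-inactivation and Y-linked transcripts were present in both mixed-sex pools, with Xist at 19.9 ± 4.82 TPM, Eif2s3y at 34.8 ± 5.94 TPM and Ddx3y at 18.7 ± 0.552 TPM. All 9 reference genes were detected, among them Gapdh at 1778 ± 43.8 TPM and Tbp at 54.8 ± 0.262 TPM. All 13 mitochondrial mRNAs were detected, led by mt-Atp6 at 4823 ± 332 TPM, and mitochondrial genes held 1.04% of gene counts in pool 1 and 1.07% in pool 2. The nuclear genome holds near-identical copies of mitochondrial genes, so these values are uncertain.

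Between the pools, genes of the subpallium list were higher in pool 1, and those of the blood, mesenchyme and dorsal midline lists were mostly higher in pool 2. A second subpallial list, described in the closing part, had a median log2 ratio of 0.00475 (percentile 34.9). All 15 subpallium members had a higher normalised count in pool 1, with a median log2 ratio of 0.49, at the 100th percentile of matched random lists. Dlx1 read 234 TPM in pool 1 and 162 TPM in pool 2, Dlx2 104 and 67.2 TPM, and the LIM factor Lhx8 43.2 and 19.6 TPM. All 11 erythroid members were higher in pool 2 by count (median log2 ratio -0.41, percentile 0), although Epb42 read 3.42 TPM in pool 1 and 3.07 TPM in pool 2. All 13 mesenchyme and meninges members were higher in pool 2 (median -0.39, percentile 0), with Col1a1 at 162 and 209 TPM. Each pool is 1 library, so these differences have no replicate check, and the percentiles describe these libraries only.

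Other lists moved with them. Choroid plexus members were higher in pool 2 in 5 of 5 cases (median -0.65), with Ttr at 42.0 TPM in pool 1 and 82.5 TPM in pool 2, and cortical hem members in 5 of 6 cases (median -0.38). Bmp4, a hem member, was higher in pool 2 by count but read 10.4 TPM in pool 1 and 6.77 TPM in pool 2. Pallial members were higher in pool 2 in 9 of 12 cases (median -0.14), Bmp pathway members in 8 of 10 (median -0.15) and glutamate genes in 5 of 7 (median -0.28). With the log2 ratio of TPM + 1 the Bmp median was -0.05, at percentile 7.42, and the glutamate median -0.15, at percentile 6.8, so neither list lay outside the central 95% there. Radial glia genes (median 0.15), postmitotic neuron genes (median 0.14) and neuronal BAF subunits (median 0.17) were higher in pool 1. With spike-in totals as the scaling, the median of all genes moved to -0.17, and the radial glia, neuron and neuronal BAF medians to -0.01, -0.03 and 0.01, with percentiles among matched lists of 99.97, 99.99 and 98.6, against 98.59 for neuronal BAF subunits before. Eye (-2.004), skeletal muscle (-1.37), sensory ganglia (-0.69), Wnt (-0.06) and sex-linked (-0.14) lists were also outside the central range, and the eye, skeletal muscle and sensory ganglia lists each had only 1 member detected in both libraries. With the log2 ratio of TPM + 1 the eye median was -0.33 (percentile 3.35) and the sensory ganglia median -0.04 (percentile 61.1), and against protein-coding genes only the sex-linked median was -0.05 (percentile 19.45), so these 3 lists lay inside the central 95% there. In all, 16 of 42 lists lay outside the central 95%. The 2.1 lists expected by chance hold only for independent lists of genes that vary independently. Members of a list can move together between 2 libraries, and some lists share members, so this is no chance rate for these lists. The endothelium median was 0.00, at the 55.6th percentile, and the S phase median 0.05, at the 59.6th. All 16 G2 and M phase members were higher in pool 1, yet their median of 0.08 lay inside the central 95% (percentile 91.3). A shared sign over all members therefore does not by itself place a list outside that range.

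**Figure D2:**
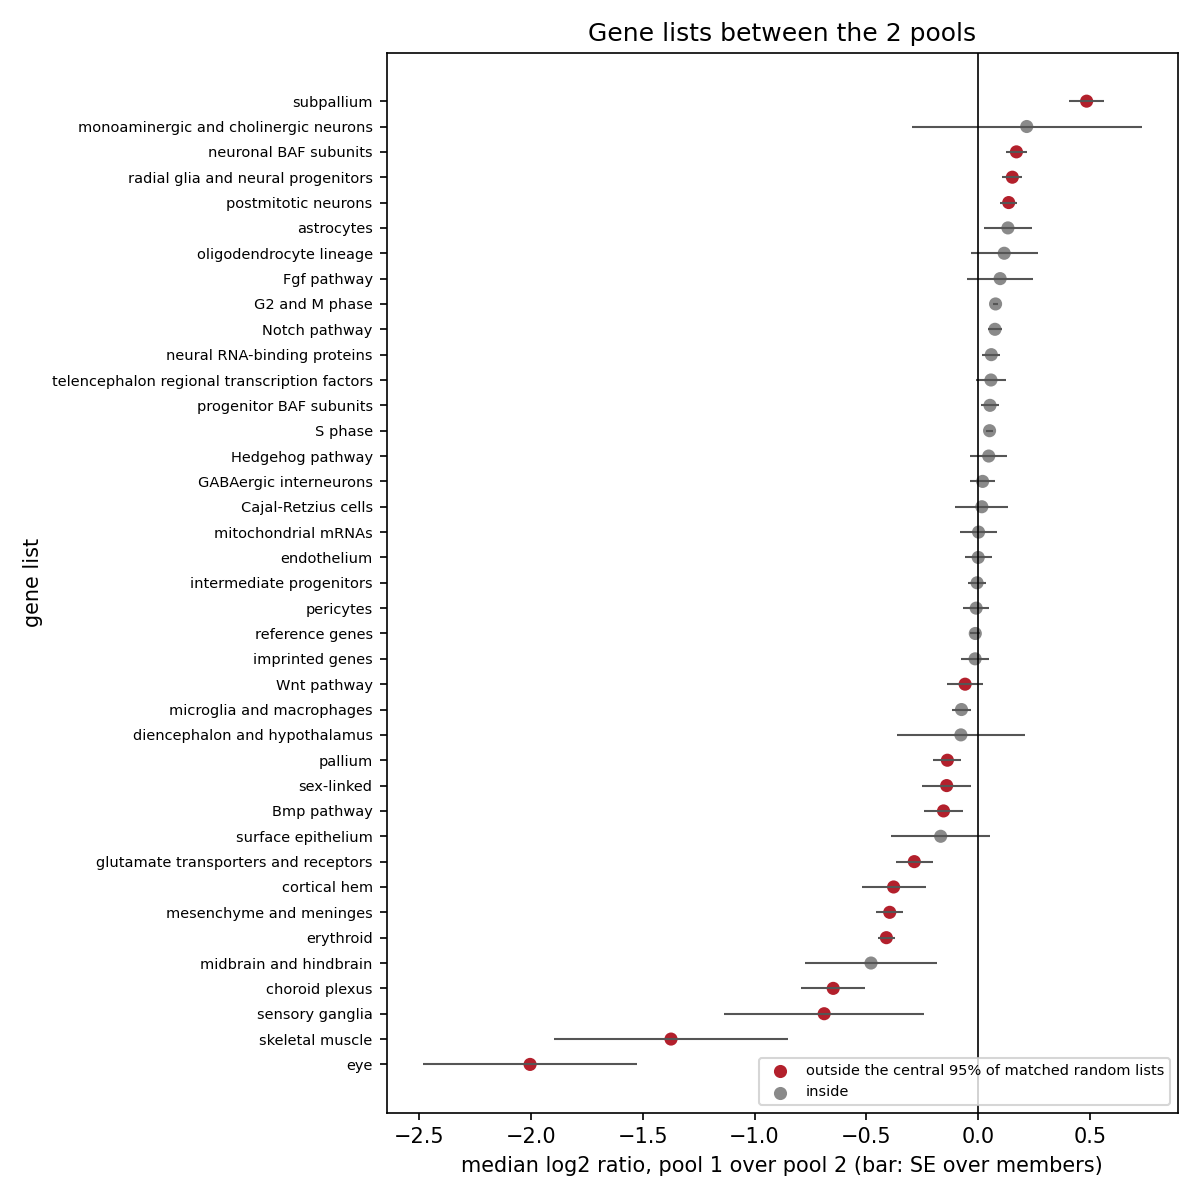
The x axis gives each list's median log2 ratio of normalised counts, pool 1 over pool 2, for lists with at least 4 tested members. Bars are standard errors over members, the members' SD over the square root of their number. They belong to a mean over genes and give no spread between pools. Red lists lie outside the central 95% of matched random lists, with subpallium at 0.49 and erythroid at -0.41.

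**Figure D3:**
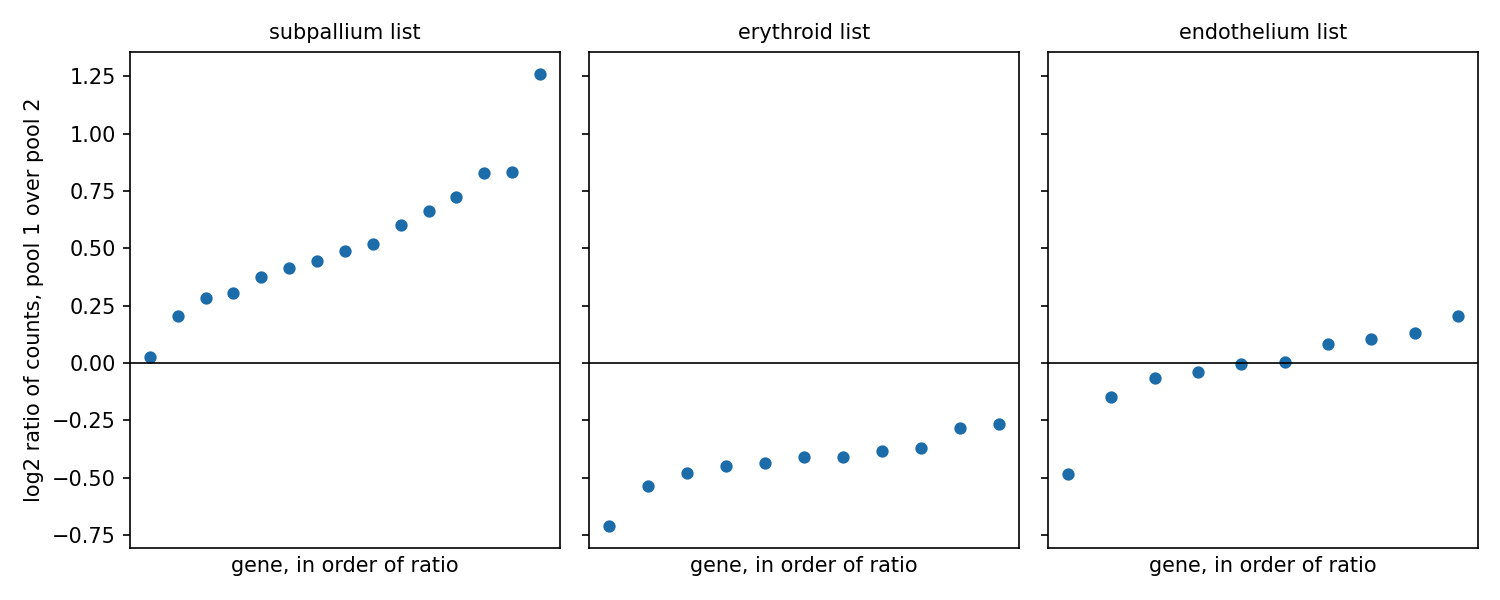
Each point is 1 gene, and the y axis gives its log2 ratio of normalised counts, pool 1 over pool 2. All 15 subpallium genes lie above 0 and all 11 erythroid genes below it, and 5 of 10 endothelium genes lie on either side.

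Few protein-coding genes differed by over 2-fold. Of 9021 with a mean TPM of at least 10, 1 was over 2-fold higher in pool 1 and 6 in pool 2. The first was Lhx8 (chromosome 3, 154306294 to 154330659), with 1379 counts in pool 1 and 606 in pool 2, a ratio with an exact 95% interval of 2.18 to 2.64. Phc2, a Polycomb subunit (chromosome 4, 128654702 to 128752881), had 2269 counts in pool 1 and 5913 in pool 2, with a ratio of pool 2 over pool 1 between 2.36 and 2.60. Hist1h2ah read 5.45 and 17.2 TPM, and near-identical histone genes make it uncertain. The ubiquitin ligase Cop1 and the cardiolipin synthase Crls1, chosen after their values were seen, had 1254 and 323 counts in pool 1 and 2992 and 811 in pool 2. The other extremes of the ratio were short or repeated RNAs, among them Gm27624 with 112 counts in pool 1 and 11.1 in pool 2, and the pseudogenes Gm15899, Gm47441, Gm15432, Gm10163 and Gm47965. Gm23167 rested on 0 and 2 counts.

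The 2 gene annotations gave close values for most genes. Over 42462 genes in both, log2(TPM + 1) correlated with r = 0.995 in pool 1 and r = 0.994 in pool 2, across genes. Of 9562 genes with a mean TPM of at least 10 in either, 276 (2.89%) differed by over 2-fold in both libraries, 186 higher in the newer and 90 higher in the older. Usp50 read 2.67 TPM in the newer annotation and 201 TPM in the older, and the pseudogene Gm10774, which overlaps it on chromosome 2, read 59.5 and 0 TPM. Ptp4a1 (ENSMUSG00000026064) read 4.78 and 308 TPM, while a second identifier with the same symbol held 287 TPM in the newer. Nupl1 read 0.025 and 48.5 TPM, Gm6565 0 and 89.6 TPM and Gm7292 0.245 and 101 TPM. In the other direction the kinase gene Ulk4 read 141 and 6.04 TPM, Gm6361 87.0 and 0 TPM, Gm5537 26.4 and 0 TPM and Gm5616 73.4 and 2.29 TPM. Of 418 genes in the fixed lists 3 differed this far, Ndn (211 and 513 TPM), Elavl1 (242 and 118 TPM) and Myt1l (42.9 and 12.2 TPM), named after their values were seen.

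Among 15 genes whose transcripts were followed, 13 had the same leading transcript in both pools. Tubb3 held 100% of its TPM in 1 of its 2 annotated transcripts. Sox2 has only 1 annotated transcript, so its share of 100% and its place among the 13 were fixed in advance. Pkm, pyruvate kinase, held 84.5% ± 0.372 (SD, n = 2) in Pkm-201 and Cdc42 82.5% ± 0.774 in Cdc42-202. Ptbp2 held 66.7% ± 1.77 in Ptbp2-201, with 18.3% in pool 1 and 19.3% in pool 2 in a transcript annotated for nonsense-mediated decay. Nova1 held 69.7% ± 3.65, Mapt 51.2% ± 2.69, Numb 43.2% ± 0.495, Map2 40.6% ± 2.86, Foxp1 31.6% ± 1.65 and Pax6 28.3% ± 1.18. By counts in place of TPM the same transcripts held 96.6% for Nova1, 28.6% for Mapt, 60.8% for Numb, 54.7% for Map2, 21.2% for Foxp1, 35.2% for Pax6, 88.7% for Ptbp2 and 65.0% for Dcx-201, and in the older annotation Nova1 and Ptbp2 held 100%, so these shares depend on the unit and the annotation. The leading transcript differed between pools for Dcx, where Dcx-201 held 37.1% and 45.3% and Dcx-203 44.7% and 33.5%, and for Gria2, where Gria2-202 held 33.2% and 26.2%. Actb held 53.9% ± 4.17 of its TPM in Actb-209, a non-coding transcript of 241 bases that held 8.44% of its counts.

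**Figure D4:**
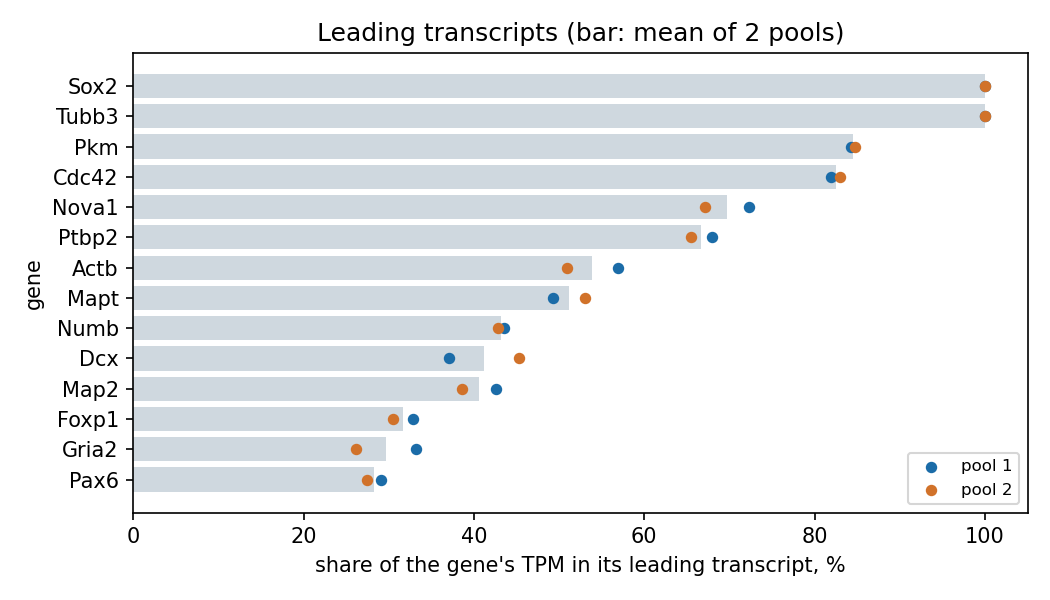
For the genes given in the text, the x axis gives the share of a gene's TPM in its leading transcript in percent, with bars at the mean of the pools and points for pool 1 (blue) and pool 2 (orange). Shares run from 28.3% for Pax6 to 100% for Tubb3 and for Sox2, which has only 1 annotated transcript, and the pools differ most for Dcx.

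ERCC spike-ins held 3.58% of counts in pool 1 (exact 95% binomial interval 3.578 to 3.591) and 3.28% in pool 2 (3.276 to 3.287), a mean of 3.43% ± 0.214 (SD, n = 2). In TPM they held 8.73% and 7.82%. Of 96 spike-ins, 83 had a count above 0 in pool 1 and 89 in pool 2.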

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

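The tests on endothelial genes and on Phc2, Cop1 and Crls1 below were chosen after the results were seen. The patterns themselves were noticed among 42 lists in these 2 libraries, and the explanations weighed are the make-up of the dissected tissue, GC content and length, and read assignment. Beyond tissue make-up no biological explanation was tested, since the design names 1 group.

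Entries that carry only a number and name no gene held 19.88 counts in pool 1 and 32 counts in pool 2. They lie outside every comparison above, and their origin was not tested.

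The subpallium list was higher in pool 1, with a median log2 ratio of 0.49 over 15 members (standard error over members 0.08). Here and below, a standard error over members is the members' SD over the square root of their number. It belongs to a mean rather than a median, treats genes as independent and gives no spread between pools. GC content and transcript length were fitted over all genes. The list's median after the fit was 0.55 (standard error 0.08), at the 100th percentile of matched lists, so the trend they describe did not reduce the shift. A larger share of subpallial tissue in pool 1 was the candidate explanation, and a second list of 11 subpallial genes was predicted, before its values were seen, to lie above the central 95% of matched lists. It did not: its median was 0.00475 (standard error 0.115), at the 34.9th percentile, with 6 members higher in pool 1 and 5 in pool 2. A further condition on the spread was added after this value was seen, and it made a reading against that explanation harder to reach. Its highest members, Dlx1as (0.69) and Dlx6os1 (0.50), overlap Dlx1 and Dlx6 and are not independent of the first list, while Vax1 stood at -0.70. Several members are also expressed outside the subpallium, so the second list cannot decide whether pool 1 held more subpallial tissue. Within the first list the log2 ratios ran from 0.03 (Gsx1) to 1.26 (Lhx8), so its members did not rise alike. The fixed GABAergic interneuron list had a median log2 ratio of 0.02 (percentile 71.6), with 4 members higher in pool 1 and 3 in pool 2. It was not set as a test of this explanation. A larger share of all or part of the subpallium in pool 1 stays open.

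The erythroid list was higher in pool 2, with a median log2 ratio of -0.41 (standard error over members 0.04). After the fit of GC content and length it was -0.33 (standard error 0.04), at percentile 0, so part of the shift moved with that trend and most did not. A higher share of every non-brain cell type in pool 2 could give this. The endothelium median was 0.00115 (standard error 0.061), a value already known when it was chosen for this comparison. With mesenchyme and meninges at -0.39, it shows only that such lists did not all shift alike. Endothelial cells also lie within the forebrain, so their list cannot decide whether pool 2 held more attached tissue. A difference in blood and mesenchyme between dissections, or in the pools' embryos, stays open and was not tested.

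Phc2, Cop1 and Crls1 were 2.47, 2.26 and 2.38-fold higher in pool 2. If read assignment specific to the newer annotation could explain this, the older annotation would differ, but the smallest of the 3 folds there was 2.28. Both annotations were applied to the same libraries, so read assignment shared by both stays open. Other technical explanations were not tested, and with 1 library per pool a difference in library preparation stays open.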

How the results depend on the processing

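The protein-coding background for random lists and spike-in totals for the coefficient of variation were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because there is 1 group. The counts of detected genes, of lists with a median of at least TPM 1, of lists outside the central 95% (12 to 18) and of genes that differ between annotations (276 to 378) stayed within 1.5 times of each main value. Among pool shifts, eye, glutamate, Bmp and sensory ganglia lists (log2 ratio of TPM + 1) and sex-linked genes (protein-coding background) lost their place outside the central 95%, the Fgf list gained it (older annotation), and imprinted genes gained it on opposite sides, below with the older annotation or no filter and above with the protein-coding background (0.12 over 13 of 16 members, against -0.01). Among lists outside the central 95%, spike-in totals turned the sign of radial glia (-0.0095) and postmitotic neurons (-0.0257). Some medians inside it turned too, such as G2 and M phase (0.079 to -0.085) and endothelium (0.00115 to -0.162). Percentiles stayed nearly unchanged, since spike-in totals lower every gene in pool 1. The correlation of the libraries was 0.964 with a pseudocount of 0.1, 0.994 without a filter, 0.994 with posterior mean TPM and 0.989 with FPKM. DESeq2's median gene-wise dispersion gave a coefficient of variation of 0.01%, which is the tool's lower limit, because 51.5% of genes sat there, so this value does not measure the spread, and spike-in totals gave 12.85%. Telencephalon minus midbrain and hindbrain was 7.70 with a pseudocount of 0.1, 5.43 with the older annotation, 5.11 with posterior mean TPM and 4.79 with FPKM, and gave no value with members of TPM 1 or more, since none was left. Radial glia minus postmitotic neurons was -0.0826, -0.0341 and -0.44 with a pseudocount of 0.1, the older annotation and the median of members. Radial glia minus astrocytes was 5.21, 3.94, 3.85, 5.39 and 2.26 with a pseudocount of 0.1, posterior mean TPM, FPKM, the median, and members of TPM 1 or more. The median of members gave 1.58 for progenitor minus neuronal BAF subunits and 2.87 for neurons minus mesenchyme. Pallium minus subpallium was 0.31 without replicate 1 and -0.33 without replicate 2. The erythroid sum was 18525 TPM when rescaled over nuclear protein-coding genes, the ERCC share 8.27% in TPM, and the correlation of the annotations 0.995 with a pseudocount of 0.1 and 0.994 with posterior mean TPM. The median leading transcript share was 53.9%, 67.0% in the older annotation, 65.0% by counts, and 53.1% to 56.9% leaving out 1 library. Where no cause is given it was not tested. Between pools 747 of 6197 genes between TPM 1 and 10 differed by over 1.5-fold, against 9 of 1765 above TPM 100.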

Other observations

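The lists in this part were written after the data were first examined and before their own values were seen. Glycolytic genes were all detected (16 of 16), led by Pkm at 1428 ± 5.86 TPM (SD, n = 2), Eno1 at 1022 ± 31.3 TPM and Ldha at 821 ± 33.6 TPM, and the list's median of 155 TPM lay at the 100th percentile of random lists. The neuronal enolase Eno2 stood at 8.26 ± 0.064 TPM. Pkm, Eno1 and Ldha have processed pseudogenes, so their counts are uncertain.

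Genes of early developmental timing, which encode RNA-binding proteins and the chromatin proteins Hmga1 and Hmga2, were present at unequal levels. Hmga1 stood at 173 ± 7.31 TPM, Igf2bp1 at 78.4 ± 2.49 TPM, Igf2bp2 at 81.3 ± 1.58 TPM, Igf2bp3 at 80.5 ± 4.80 TPM and Hmga2 at 38.1 ± 0.212 TPM, while Lin28b at 12.7 ± 0.071 TPM exceeded Lin28a at 0.955 ± 0.332 TPM. Among DNA methylation genes the maintenance factors Uhrf1 at 150 ± 5.83 TPM and Dnmt1 at 112 ± 10.2 TPM stood beside the de novo enzyme Dnmt3a at 111 ± 3.80 TPM, and Dnmt3b was at 7.77 ± 0.877 TPM. Tet3 at 53.5 ± 6.22 TPM exceeded Tet1 at 29.6 ± 1.56 TPM and Tet2 at 19.1 ± 0.849 TPM. All 19 axon guidance genes were detected, led by the ephrin receptors Epha3 at 64.1 ± 5.43 TPM and Epha5 at 50.6 ± 4.14 TPM, and this list had a pool ratio at the 1.38th percentile (median log2 ratio -0.03), but at the 11.24th percentile (median -0.006) in the older annotation. Of 6 histone deacetylases Hdac2 was highest at 360 ± 11.3 TPM, then Hdac1 at 167 ± 7.04 TPM.

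RNAs that are not typical polyA products were abundant, chosen after their values were seen. The signal recognition particle RNAs Rn7s1 and Rn7s2 each read 7636 ± 344 TPM, with identical values because the copies share reads, and the ribosomal entry CT010467.1 read 6568 ± 309 TPM. Annotated rRNA held 0.692% of gene counts in pool 1 and 0.745% in pool 2. In the older annotation it held 7.08e-05% and 8.05e-05%, so this share depends on the annotation. Replication-dependent histone genes summed to 6141 ± 158 TPM over 66 genes, of which Hist1h2ap alone held 4835 TPM.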
